A study of Mus musculus with 12 samples.

How the data were processed

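Total RNA from primary mammary epithelial cells was turned into biotinylated cRNA and hybridised to single-colour Affymetrix arrays, per the labels' protocols. RNA was extracted with Trizol and cleaned on columns. The deposited table holds 1 intensity per probe set and array on a linear scale, for 12 arrays and 45101 probe sets. The submitters' processing notes name MAS5, and its version and scaling target are not given in the sources used here. From the values, the 2% trimmed mean was nearly the same on all arrays (999.7), so each array had been scaled to 1 target, while the medians ran from 187 to 210.5. Values ran from 0.1 to 64224.3 with 0 values at zero. MAS5 values near the bottom of this range are noisy, and scaling by a trimmed mean leaves differences in the shape of the distribution between arrays. An array has no read depth, and the number of arrays, 6 per group, limits the precision.

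Groups and replicate numbers were taken from the sample titles. Probe sets were named through the platform's annotation and the symbols were checked against a RefSeq gene table of the mouse assembly GRCm38.p6 by Entrez ID, which changed 0 symbols. Of 45037 probe sets other than the array's own controls, 34945 had 1 symbol, 932 had several and 9160 were unnamed here. No gene was named from a probe set with several symbols. No genome build is given for the array, so no coordinates are printed.

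The intensities were used as deposited, as log2(value + 16). A fold on this scale understates the change of dim genes. Probe sets whose mean log2 value lay at or above the 40th percentile were kept, a level of about 101 intensity units, which left 27022. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment over these probe sets and a threshold of 0.05. No batch or scan date is used here, since the labels give none.

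Gene lists for pathways and cell types were written down beforehand, 37 in all. A gene was read by its brightest probe set, and lists with at least 5 measured members were tested, which left out the red blood cell list. The values of 1 tested list are not reported here. Lists were tested with limma's fry (directional p), Benjamini-Hochberg over 36 lists, and means per array with an exact permutation test over all 924 assignments of 6 against 6 arrays. Fry asks whether the genes of a list move one way on balance and does not compare a list with other genes. Intervals are the shifts that the exact two-sided test at 95% does not reject. The smallest exact p is 0.00216.

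Genes named in the text are all Arhgap5 probe sets and the 12 largest rises and 12 largest falls past the threshold by probe sets with 1 symbol. Where fewer than 5 passed in a direction, the 5 smallest unadjusted p in that direction were added and are said not to pass. From lists that passed, up to 4 members were to be named, and from other lists up to 3 members past the threshold. Other list members given as examples were picked after their values were seen. The design, the lists, this rule and the first set of other settings were fixed before the data were examined.

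That first set held pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalisation, equal medians, eBayes without trend or with robust estimation, array weights, the replicate number as a block, 1 probe set per gene, other thresholds, other list tests and leaving out each array in turn. Covariates (the lymphocyte markers, the 3′ over 5′ ratios and the hybridisation controls) and a fit without p190B replicates 1 and 3 were added after seeing the data.

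The limma steps were tested on simulated data with the real probe sets' levels and spread, 6 arrays against 6, in 20 runs with 200 of 27022 probe sets changed. For the comparison of p190B with control they recovered 55.4% of 1.5-fold changes, 87.5% of 2-fold changes and 97% of 4-fold changes. The real data gave only 10 calls, and the Benjamini-Hochberg cutoff loosens as more probe sets pass. These shares can therefore overstate recovery in the real comparison. Of the 20 runs with no change, 1 gave any call, and it gave 1751. A 1.5-fold shift of the 20 integrin genes was found by fry in 20 of 20 runs, and 2 of 20 runs with no change called any list. No other list was shifted in this way. The integrin mean spanned 0.35 log2 units over the arrays, against 1.50 for the cell cycle list and 3.26 for the T and NK list. Recovery of the integrin shift therefore does not carry over to such variable lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.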

Results

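Gene expression was measured in mammary epithelial cells isolated from female FVB/N mice, an inbred laboratory strain. The p190B group, 6 arrays, carried 2 transgenes: MMTV-rtTA, which makes a doxycycline-responsive activator in the mammary epithelium, and a tetracycline operator driving p190B together with luciferase. The control group, also 6 arrays, carried MMTV-rtTA alone. p190B, encoded by Arhgap5, is a GTPase-activating protein. Mice of both genotypes ate chow with 2 g/kg doxycycline for 7 days from 5 weeks of age, and their cells were isolated at 6 weeks. The comparison asks which transcripts differ in mammary epithelial cells between doxycycline-fed mice with and without the p190B transgene. The labels describe the arrays of each group as biological replicates, 1 per array. Values are linear intensities of 45101 probe sets per array, and the number of arrays limits the precision. Over the tested probe sets the median standard error of a log2 difference was 0.124. Pairs of arrays correlated between 0.964 and 0.981 across probe sets, with a median of 0.976 within genotypes and 0.975 between them.

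The transgene's own gene was examined first, because it checks the genotype labels. Arhgap5 was read by 4 probe sets, and they did not move together. Probe set 1423194_at averaged 1344 ± 153 intensity units in p190B cells against 1014 ± 182 in control cells (SD, n = 6 each), a log2 difference of 0.41 (SE 0.11). The other Arhgap5 probe sets gave −0.32 for 1450896_at, −0.14 for 1450897_at and 0.10 for 1457410_at. The brightest of them, 1450897_at, averaged 4619 ± 759 in p190B and 5050 ± 412 in control (SD, n = 6 each).

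Arhgap5 did not pass the test over all probe sets, so this check leaves open whether p190B RNA was raised on these arrays. The limma adjusted p was 0.258 for 1423194_at, 0.491 for 1450896_at, 0.710 for 1450897_at and 0.925 for 1457410_at. In an exact two-sided permutation test adjusted over the 4 Arhgap5 probe sets alone, 1423194_at reached p = 0.0346 and 3 of 6 p190B arrays lay above every control array. The log2 difference of 1423194_at was 0.23 with the Gapdh 3′ over 5′ ratio as a covariate, and that of 1457410_at was −0.04 without p190B replicate 3. The difference of 1457410_at was also negative with either ratio as a covariate and without p190B replicates 1 and 3. That of 1450897_at ran from −0.21 to −0.087 when any single array was left out, and was −0.30 with the Actb ratio as a covariate, −0.32 with the Gapdh ratio and −0.27 without p190B replicates 1 and 3. Which part of the Arhgap5 transcript each probe set reads, and which untranslated sequence the transgene carries, is not given in the sources used here.

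**Figure D1:**
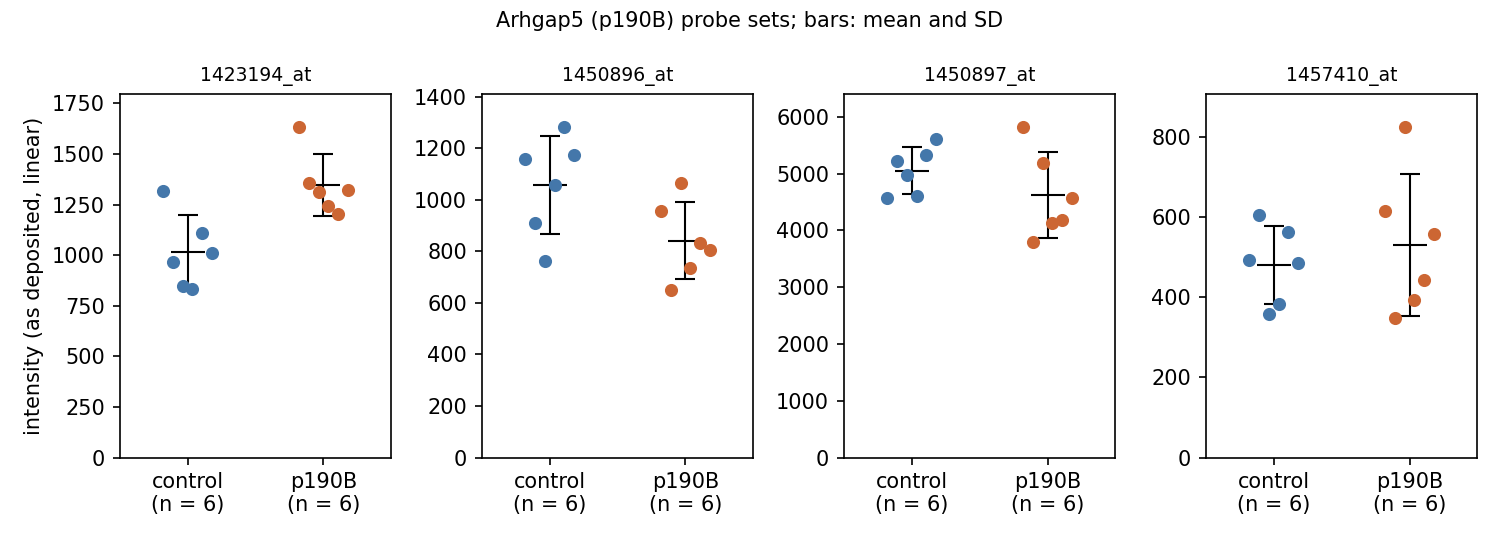
Intensity (linear, as deposited) of each Arhgap5 probe set on each array, control in blue and p190B in orange, with group mean and SD (n = 6 each). The p190B mean lies above the control mean for 1423194_at (1344 against 1014) and below it for 1450896_at (840.5 against 1057).

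Across the arrays, p190B cells had lower signal for 8 named genes and higher signal for 1, each by 1 probe set. Other tested probe sets of these genes, given below, moved less or the opposite way. Tor1aip2, an endoplasmic reticulum membrane protein that activates torsin ATPases, fell by 0.69 on the log2 scale (SE 0.09), from 5345 ± 747 intensity units in control to 3286 ± 318 in p190B (SD, n = 6 each). Tagln2, the actin-binding protein transgelin-2, also fell by 0.69 (SE 0.08), from 15883 ± 758 to 9895 ± 1277. Zfp644, a zinc finger protein, fell by 0.67 (SE 0.08) and Bloc1s4, a subunit of a complex that builds lysosome-related organelles, by 0.61 (SE 0.07). Vdac1, the main channel of the mitochondrial outer membrane, rose by 0.40 (SE 0.05), from 12076 ± 417 to 15998 ± 881.

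The other genes with a lower probe set were Mettl14, a subunit of the RNA N6-adenosine methyltransferase (−0.60, SE 0.09), and Cox6c, a subunit of cytochrome c oxidase (−0.37, SE 0.06). Ncoa4, the receptor that delivers ferritin to lysosomes, followed at −0.33 (SE 0.05), and the translation initiation factor Eif4g2 at −0.24 (SE 0.04). Eif4g2 was the brightest of these, at 29123 ± 877 in control and 24667 ± 622 in p190B (SD, n = 6 each). A further probe set that the annotation does not name, 1424020_at, fell by 0.64 (SE 0.10). Each of these 10 probe sets separated the genotypes fully, with 6 of 6 p190B arrays beyond all control arrays. The exact permutation p was 0.00216, the smallest that 6 arrays against 6 allow. It is not adjusted over the 27022 tested probe sets. The 10 were picked by their limma p on these same arrays, so their separation is no independent evidence.

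Next in rank among higher probe sets stood Tnrc6a, a scaffold of microRNA silencing (0.39, SE 0.06), and Lamtor1, which anchors the Ragulator complex to lysosomes (0.28, SE 0.05). Vcp, an ATPase that extracts ubiquitylated proteins, gave 0.23 (SE 0.04), and Lonp2, a peroxisomal protease, 0.51 (SE 0.10). These 4 did not pass, with limma adjusted p from 0.0592 for Tnrc6a to 0.125 for Lonp2, although each had 6 of 6 p190B arrays above all control arrays. They too were picked by their limma p on these arrays, so that separation is no added evidence.

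In all, 10 of 27022 tested probe sets passed a limma adjusted p of 0.05, 1 higher and 9 lower in p190B. The adjusted p was 0.00404 for Tagln2, Vdac1, Zfp644 and Bloc1s4, 0.0161 for Tor1aip2 and 0.0406 for Mettl14, Cox6c, Ncoa4, Eif4g2 and 1424020_at. At an unadjusted p under 0.05 there were 2518 probe sets (9.32%), 1219 higher and 1299 lower, where 1351 are expected on average by chance. Probe sets vary together across arrays, so a chance count can lie far from this average: 1 simulated run with no change gave 1751 adjusted calls. The spread of the unadjusted count was not measured, so its excess is no evidence of further genotype effects. At an adjusted p under 0.10 the count was 24, of which 22 were lower. Quantile normalisation gave 31 probe sets, 9 of them higher, and scaling every array to the same median gave 3, none of them higher. The limma count was 0 with the Gapdh 3′ over 5′ ratio as a covariate (1802 at an unadjusted p under 0.05), 1 with the Actb ratio, 5 without p190B replicates 1 and 3, and between 4 and 9 when any single array was left out. Tagln2, Vdac1, Zfp644 and Bloc1s4 passed in all 12 fits that left out 1 array. Tor1aip2 passed in 6 of them, Cox6c in 2, and Mettl14, Ncoa4 and Eif4g2 in 0.

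Each called gene passed by 1 probe set only. For 8 of the 9 named genes other probe sets of the same gene were also tested, 17 in all, and their log2 differences ranged from −0.23 to 0.20. The second Tagln2 probe set, 1426529_a_at, gave 0.09 (SE 0.05) beside the fall of 0.69 in 1439407_x_at. For Tor1aip2 the other probe sets gave −0.07, 0.02 and −0.08, and for Cox6c the brighter probe set gave 0.06 (SE 0.06). Vdac1 had 1 further probe set at an unadjusted limma p under 0.05, 1436992_x_at with 0.20 (SE 0.04), and others at −0.01 and 0.02. Mettl14 had no other tested probe set.

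**Figure D2:**
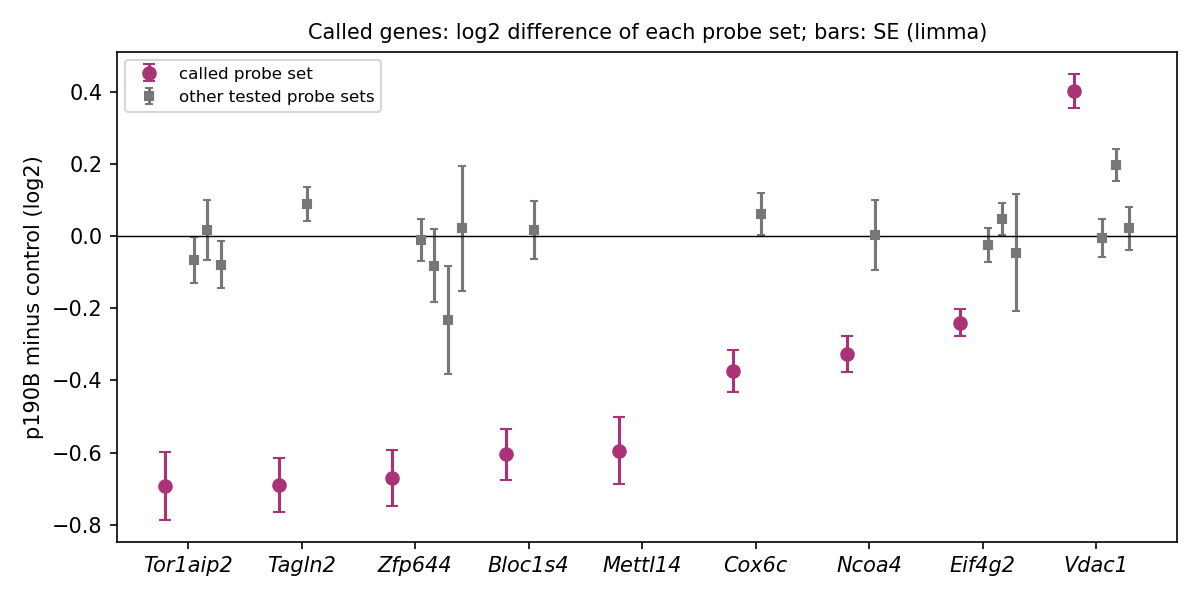
Log2 difference, p190B minus control, of the called probe set (purple circles) and the other tested probe sets (grey squares) of each called gene, with limma standard errors (n = 6 arrays per group). The other probe sets lie between −0.23 and 0.20, while the called ones lie between −0.69 and 0.40.

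None of the gene lists fixed for this tissue and transgene passed the test for a shift between genotypes. Actomyosin and SRF target genes averaged −0.01 on the log2 scale (95% exact permutation interval −0.10 to 0.09) over 24 measured members, and integrins and focal adhesion genes 0.01 (−0.10 to 0.12) over 20. The list with the largest average difference was cell cycle and proliferation, at 0.28 (−0.26 to 0.81), where 28 of 31 members were higher. It ran from 0.15 to 0.41 when any single array was left out, and was 0.59 with the Actb ratio as a covariate, 0.51 with the Gapdh ratio and 0.49 without p190B replicates 1 and 3. Averages under other settings were followed only for the cell cycle, interferon, macrophage, extracellular matrix and TGF-beta lists. Of these, the interferon response list was higher than the cell cycle list without control replicate 2 (0.18 against 0.15) and without control replicate 6 (0.219 against 0.207). It was also higher with the hybridisation controls as a covariate (0.242 against 0.239). The extracellular matrix list was slightly higher than the cell cycle list without control replicate 2 (0.14977 against 0.14976). Whether other lists overtook it was not checked.

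Of the 36 lists tested, 0 passed fry, limma's directional list test, with a smallest adjusted p of 0.993, and 0 reached an unadjusted p under 0.05. Exact permutation of the list means also gave 0, camera with an estimated correlation 0 and camera with a preset correlation 1, the cell cycle list (adjusted p = 0.00148). That list had an adjusted p = 0.962 with an estimated correlation. None of the measured members in any list passed over all probe sets, each gene being read by its brightest probe set.

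By limma, the pass counts adjusted over the list alone were 1 of 24 actomyosin genes, 1 of 20 integrin genes, 1 of 15 luminal epithelial genes, 1 of 25 junction genes and 2 of 31 chemokines and cytokines. Myh9, the heavy chain of nonmuscle myosin IIA, gave 0.28 (SE 0.06), and its 4 other tested probe sets gave 0.06, −0.19, 0.01 and 0.04. Itgb8, the integrin beta 8 subunit, gave −0.36 (SE 0.09). Cdh1, which encodes E-cadherin, gave −0.48 (SE 0.13) and belongs to both the luminal and the junction list, with 13968 ± 2539 units in control and 9965 ± 1636 in p190B (SD, n = 6 each). Ccl11, an eosinophil attractant, gave −0.39 (SE 0.10) and Osm, the cytokine oncostatin M, 0.60 (SE 0.16). Over all probe sets 0 of these passed, with limma adjusted p from 0.155 for Myh9 to 0.233 for Cdh1.

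The epithelial lineage lists had intervals on both sides of 0. Luminal epithelial markers averaged 0.07 (95% exact permutation interval −0.15 to 0.30), luminal progenitor and alveolar markers 0.05 (−0.16 to 0.27), mature luminal hormone-sensing markers 0.01 (−0.24 to 0.27) and basal and myoepithelial markers 0.01 (−0.15 to 0.17). The keratins Krt8, Krt18 and Krt14, markers of luminal and basal cells named after their values were seen, gave 0.03 (SE 0.05), 0.16 (SE 0.06) and −0.01 (SE 0.14). Cell junction and polarity genes averaged −0.04 (−0.27 to 0.20) and epithelial to mesenchymal transition factors −0.03 (−0.20 to 0.17). Of the basal list the median was −0.01, opposite in sign to its mean.

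Matrix and growth factor lists lay in the same range. Fibrillar collagen and extracellular matrix genes averaged 0.12 (−0.10 to 0.38), with 23 of 25 members higher, and 0.032 without control replicate 6. Their average turned slightly negative with the Gapdh ratio as a covariate. Basement membrane genes averaged 0.08 (−0.14 to 0.29) and matrix proteases 0.05 (−0.18 to 0.32). TGF-beta pathway genes averaged −0.03 (−0.15 to 0.09), and −0.13 with the Actb ratio and −0.14 with the Gapdh ratio as a covariate. IGF and insulin signalling genes averaged 0.04 (−0.04 to 0.12), EGF receptor and ERBB signalling −0.04 (−0.20 to 0.10) and Wnt and Notch signalling −0.02 (−0.09 to 0.03). Irs1, an adaptor of the insulin and IGF receptors named after its value was seen, gave 0.25 (SE 0.13) with a limma adjusted p of 0.592.

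Lists for growth, stress and metabolism gave small averages. Apart from the cell cycle list, where Mki67 gave 0.48 (SE 0.23) and Top2a 0.36 (SE 0.25), apoptosis and p53 targets averaged −0.01, the immediate early and dissociation response −0.02, hypoxia and glycolysis 0.01 and the unfolded protein response −0.02. Lipid and cholesterol synthesis averaged 0.00, circadian clock genes −0.01, ribosomal protein genes 0.04 and mitochondrial respiratory chain genes 0.04. Interferon response genes averaged 0.16 (95% exact permutation interval −0.14 to 0.48), and 0.062 without control replicate 5. Chemokines and cytokines averaged 0.07 (−0.24 to 0.39).

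No list of markers of other cell types passed, and lymphocyte markers had the widest spread between arrays. Macrophage markers averaged 0.13 (95% exact permutation interval −0.21 to 0.49), and from 0.059 without control replicate 5 to 0.21 without control replicate 3. They averaged 0.32 with either 3′ over 5′ ratio as a covariate and 0.27 without p190B replicates 1 and 3. Fibroblast markers averaged 0.05 (−0.19 to 0.32), adipocyte markers −0.06 (−0.36 to 0.25), endothelial and pericyte markers −0.06 (−0.38 to 0.29), nerve and Schwann cell markers −0.07 (−0.29 to 0.15) and neutrophil and mast cell markers −0.04 (−0.48 to 0.40). The interval for skeletal muscle markers ran from −1.09 to 0.79 around −0.15. T and NK lymphocyte markers averaged −0.01 (−1.58 to 1.48) and B lymphocyte and plasma cell markers 0.07 (−1.52 to 1.63). The mean log2 value of both lymphocyte lists together ran from 7.28 to 10.10 over the control arrays and from 6.94 to 10.15 over the p190B arrays.

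**Figure D3:**
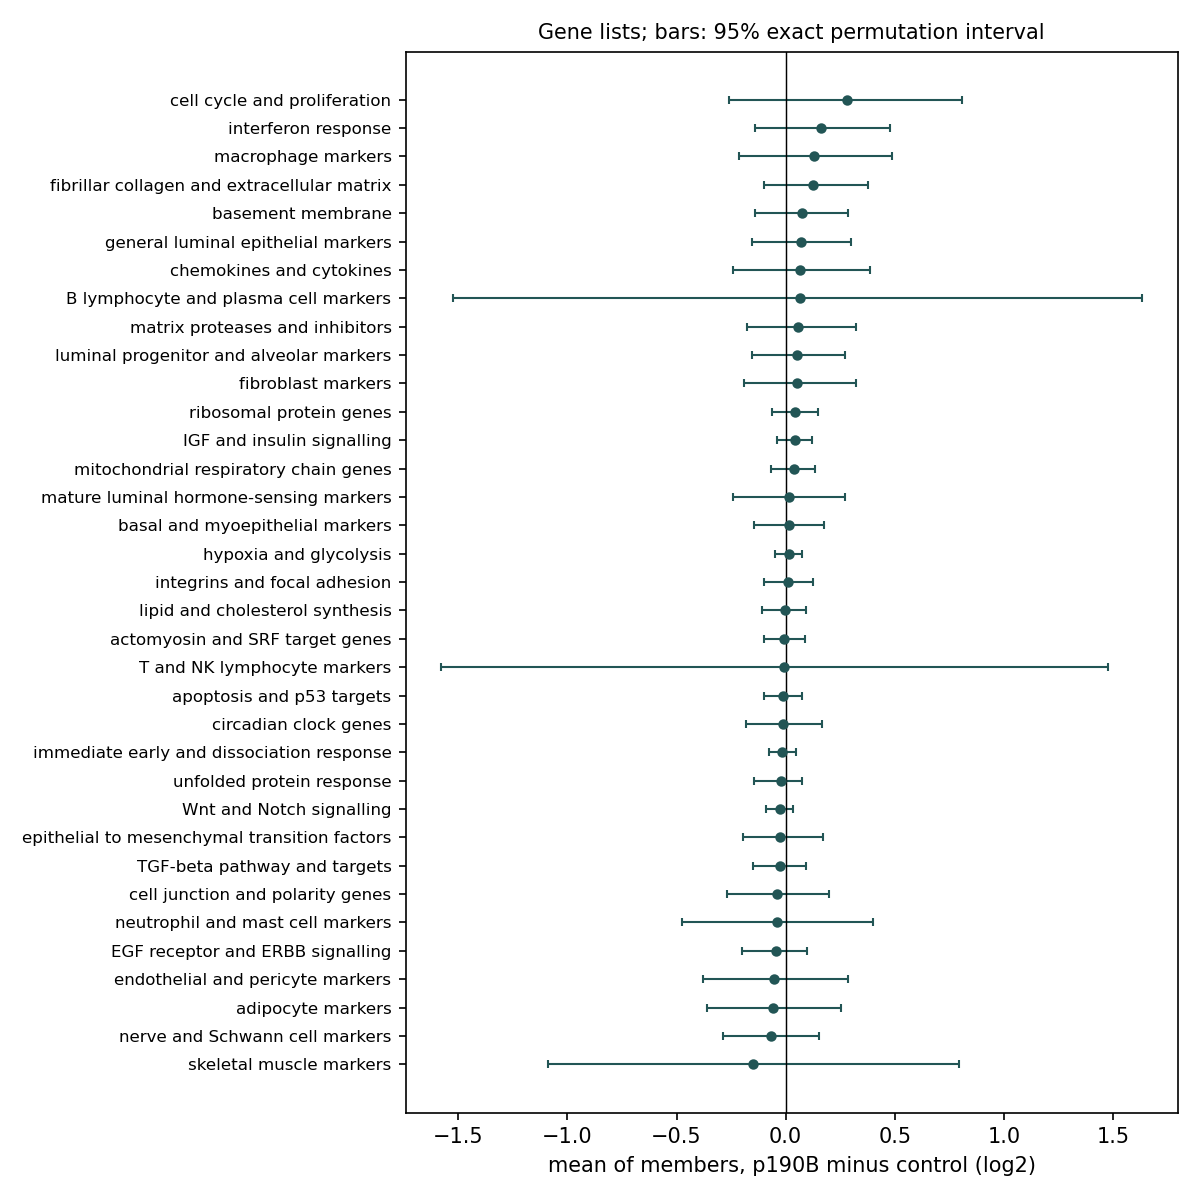
Mean log2 difference, p190B minus control, of the members of each of 35 gene lists, with 95% exact permutation intervals (n = 6 arrays per group). Every interval includes 0, and those of the lymphocyte lists are the widest, from −1.58 to 1.48 for T and NK markers.

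The control probe sets that read the ends of Actb and Gapdh differed between genotypes. The log2 3′ over 5′ ratio of Gapdh was −0.40 ± 0.06 in p190B and −0.49 ± 0.02 in control (SD, n = 6 each), a difference of 0.09. That of Actb was 0.40 ± 0.11 against 0.29 ± 0.03, a difference of 0.11. p190B replicates 1 and 3 had the highest Actb ratios, 0.48 and 0.59. The median log2 intensity per array was 7.73 ± 0.05 in p190B and 7.70 ± 0.05 in control.

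By exact two-sided permutation tests adjusted over these 3 measures, the difference passed for Gapdh (p = 0.0130) and for Actb (p = 0.0227) but not for the median intensity (p = 0.368). Without p190B replicates 1 and 3 the Gapdh difference was 0.06 and the Actb difference 0.04, which no longer passed. The Actb difference also did not pass without control replicate 3, 4, 5 or 6, at 0.11, 0.11, 0.10 and 0.11. Both ratios moved with genotype, as the called probe sets did.

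**Figure D4:**
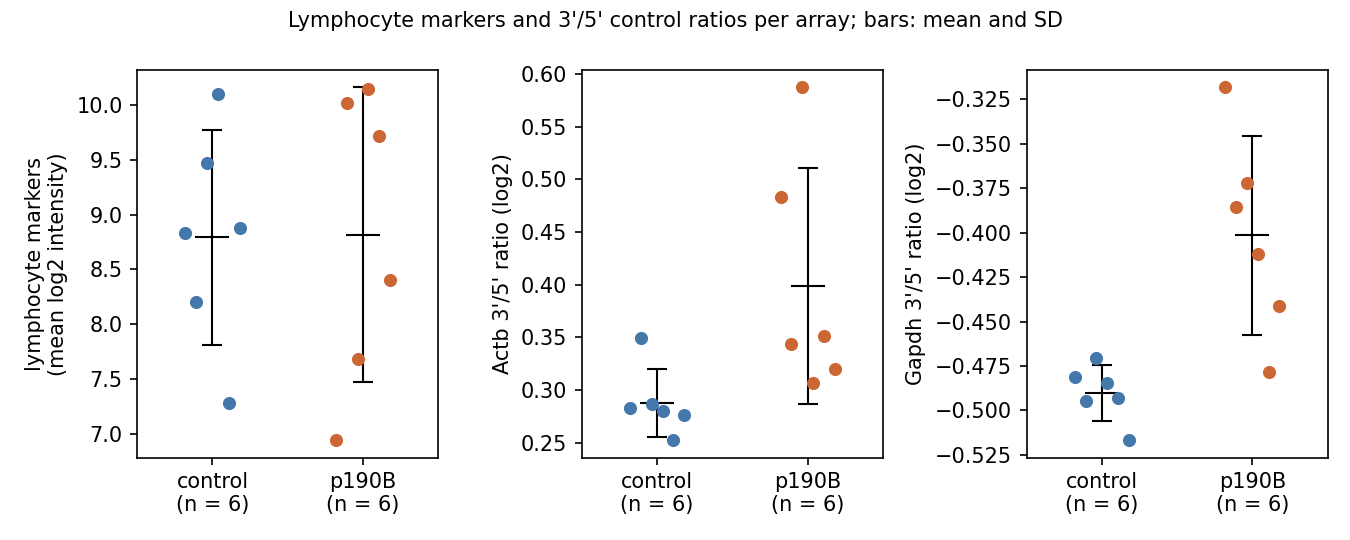
Mean log2 intensity of the lymphocyte markers (left) and log2 3′ over 5′ ratios of Actb (middle) and Gapdh (right) on each array, control in blue and p190B in orange, with group mean and SD (n = 6 each). The lymphocyte values overlap (7.28 to 10.10 in control, 6.94 to 10.15 in p190B), and the Gapdh means are −0.49 and −0.40.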

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

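Tests of the 3 patterns weighed here were chosen only after the results had been seen. Of 112 groups of 6 arrays examined for an array far from the others, 8 held one, and chance gives about 1 in 20.

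Among gene lists, the basement membrane mean of control replicate 6 was 11.54 (log2), below the range of 11.78 to 11.88 of the other control arrays. The nerve and Schwann cell mean of p190B replicate 6 was 11.45 against 11.04 to 11.19 in the other p190B arrays. Chemokines and cytokines averaged 12.11 on p190B replicate 2 against 11.48 to 11.65. The unfolded protein response mean of control replicate 2 was 12.29 against 11.97 to 12.07. Lipid and cholesterol synthesis averaged 11.48 on control replicate 5 against 11.21 to 11.28.

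Among array measures, the log2 3′ over 5′ ratio of Actb on control replicate 2 was 0.35 against 0.25 to 0.29 on the other control arrays. The median log2 intensity was 7.80 on control replicate 1 against 7.67 to 7.71, and 7.82 on p190B replicate 5 against 7.69 to 7.73. The array's control probe sets for 18S ribosomal RNA, which no comparison uses, were far above control on p190B replicate 3, at 4266.3 for the 3′, 1668.5 for the middle and 1839.4 for the 5′ probe set. p190B replicate 1 was next, at 725, 469.4 and 358, and the highest control values were 433, 331.1 and 269.5.

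The genes called between genotypes each passed by 1 probe set only. A change in the level of the whole transcript is argued against by the other probe sets of these 8 genes, whose mean shift in the called direction was 0.0030 (95% exact permutation interval −0.05 to 0.05) beside 0.50 for the called ones. The higher 3′ over 5′ ratio of the p190B arrays stays open as a cause. The mean shift of the 10 called probe sets was 0.52 (SE 0.04) without and 0.50 (SE 0.06) with the Gapdh ratio as a covariate, a fit in which 0 probe sets passed. These 10 were picked for a large genotype difference beside a small spread within genotypes. That leaves little for the ratio to explain, so this fit cannot decide. A sequence variant linked to the transgene's place in the genome is argued against as the cause of most calls, since at most 2 of the 9 genes lay on 1 chromosome. For single genes it stays open, as do variants at several places, because this count cannot exclude them. Probes that bind another transcript and a genotype effect on 1 isoform or transcript end may each give this pattern, and both stay open, since no probe sequences were used here. The sample codes in the titles run in order by genotype and the labels give no processing dates, so a difference in processing between the groups also stays open.

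Lymphocyte markers spanned 3.21 log2 units between arrays. The high 3′ over 5′ ratios of p190B replicates 1 and 3 are argued against as the whole cause, because the markers still spanned 2.87 over the other 10 arrays. A part for the ratio stays open, since the markers correlated with the Actb ratio at r = −0.761 over the p190B arrays (exact permutation p = 0.0736; Spearman rho = −0.771, exact p = 0.103) and at 0.0318 over the control arrays (exact p = 0.938; rho = 0.143, exact p = 0.803). Without the 2 farthest arrays these r were 0.145 and −0.772. A genotype difference stays open too, at 0.03 (95% exact permutation interval −1.52 to 1.54, exact p = 0.972), beside a span of 2.82 within control and 3.21 within p190B. Lymphoid cells carried into some preparations are a candidate explanation, since T and NK markers rose and fell with B and plasma cell markers over the 6 control arrays (Pearson r = 0.971, exact permutation p = 0.00278; Spearman rho = 0.943, exact p = 0.0167) and the 6 p190B arrays (r = 0.989, exact p = 0.00139; rho = 1, exact p = 0.00278). Adjusted over 8 relations these r had exact p = 0.00444 and 0.00278, those with the Actb ratio 0.0841 (p190B) and 0.938 (control), and without the 2 farthest arrays the r between the lists was 0.931 and 0.975. Further relations among the 8 set the markers against the main axis of variation between arrays, computed without these genes. Their r was 0.923 over all arrays, 0.843 over control and 0.964 over p190B arrays, so the markers followed a large part of the variation between arrays. Cd3d ran from 14.3 to 3160 intensity units, Ms4a1 from 64.7 to 2654.8 and Ighm from 548.3 to 5447.6, 1 of the 30 marker genes (Thy1) is also on another list, and the labels name no sort that would remove lymphocytes.

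The 3′ over 5′ ratios of Actb and Gapdh were higher on p190B arrays. That 2 arrays alone give the difference is argued against for Gapdh, which still differed by 0.06 without p190B replicates 1 and 3 (exact permutation p = 0.00952). For Actb it stays open, since the difference was 0.11 with and 0.042 without them (95% exact permutation interval −0.0014 to 0.081, exact p = 0.0571). On those 2 arrays degradation of the sample RNA before the poly-A control RNAs were added is argued against as the whole cause, because the ratio of these added RNAs was also raised there, to 1.19 and 1.31 against at most 1.02 on the other 10, a gap of 0.16. On the other 4 p190B arrays the added RNAs differed from control by −0.020 (95% exact permutation interval −0.12 to 0.09), an interval that includes the Gapdh difference of 0.06, so shorter labelled products there cannot be told apart from sample degradation. A genotype effect on RNA quality and a difference in processing between the groups, whose sample codes run in order by genotype, stay open and were not tested.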

How the results depend on the processing

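The covariate fits and the fit without p190B replicates 1 and 3 were chosen after seeing the data. All 9 called genes kept their direction under every setting run that gave them a value, and Arhgap5 1423194_at stayed above 0 in each. The count of called probe sets was 10 with a pseudocount of 1 or 64, 11 with robust estimation, 9 with 1 probe set per gene, 5 with no filter and 17 with the stricter filter (the number of probe sets tested differs). It was 31 (9 higher) after quantile normalisation, 3 (0 higher) with equal medians, 3 without trend and 19 with array weights, and the cause was not tested. Other thresholds gave 24 at an adjusted p under 0.10, 4 under 0.01, and 52 at an unadjusted p under 0.01 with 1.5-fold change. Covariates gave 24 (lymphocyte score, all 10 shared), 1 (Actb ratio), 0 (Gapdh ratio, limma, 1802 at an unadjusted p under 0.05) and 100 (hybridisation controls, 31 higher, all 10 shared), and leaving out p190B replicates 1 and 3 gave 5, 4 of them shared. Leaving out 1 array gave 4 to 9: 4 without control replicate 3 or 5 or p190B replicate 2, 4 or 5, 5 without control replicate 4 or p190B replicate 3, and 6 without control replicate 1 or 6. Tagln2, Vdac1, Zfp644 and Bloc1s4 passed in 12 of 12 such fits, Tor1aip2 in 6, Cox6c in 2, and Mettl14, Ncoa4 and Eif4g2 in 0.

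With the replicate number as a block the limma count was 0, with 2287 at an unadjusted p under 0.05. The values gave little sign that the numbers pair the arrays: same-number correlations ran from −0.287 to 0.408, 1 of 6 was over 0.1, and 2 of 12 arrays correlated best with their own number. Correlations over all probe sets cannot exclude that arrays of the same number were processed together. Lists passing numbered 0 in every fit run for the lists except camera with a preset correlation (1). Arhgap5 1423194_at (0.41) passed only by exact permutation over its 4 probe sets. Arhgap5 1457410_at turned to −0.27 with the Actb ratio, −0.087 with the Gapdh ratio and −0.14 without the 2 arrays, and ran from −0.036 to 0.21 when 1 array was left out. The extracellular matrix list turned to −0.016 with the Gapdh ratio. The TGF-beta list turned to 1.67e-05 with the hybridisation controls, and ran from −0.059 to 0.0054 (the highest without control replicate 2) when 1 array was left out. The Actb ratio difference was 0.042 without the 2 arrays and 0.073 to 0.13 without 1, and the median intensity difference 0.011 to 0.049, passing without control replicate 1 (exact p = 0.0390). The cause of these turns was not tested. Dim probe sets have noisy values, so small differences there were not resolved.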

Other observations

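The genes brought in by the lymphocyte covariate were chosen for description after the data were seen, as were Malat1 and the comparison of probe sets of 1 gene; the test on the other nuclear RNAs and the comparison with other splits were set before their results were seen. With the lymphocyte score as a covariate 24 probe sets passed limma's adjusted p of 0.05, 3 of them higher in p190B. Gja1, the gap junction protein connexin 43, fell by 0.68 in this fit (SE 0.10, adjusted p = 0.0262), and Cdh1, which encodes E-cadherin, fell by 0.48 (SE 0.08, adjusted p = 0.0475). Without the covariate the same Gja1 probe set gave −0.68 (SE 0.12, adjusted p = 0.0673), and 4 of its 5 other tested probe sets were also lower, at −0.24, −0.42, −0.10 and −0.28, while the fifth gave 0.36 (SE 0.48). Odc1, the first enzyme of polyamine synthesis, fell by 0.37 in the covariate fit (SE 0.05, adjusted p = 0.0144), and its 2 other probe sets gave −0.07 and −0.11 without the covariate. Sntb2, a dystrophin-associated adaptor, fell by 0.72 (SE 0.12, adjusted p = 0.0473), and its 3 other probe sets gave −0.18, −0.26 and −0.21 without the covariate. Sfpq, a nuclear splicing factor, fell by 0.50 (SE 0.08, adjusted p = 0.0473), with 5 other probe sets from −0.28 to −0.02. Not all genes brought in by this covariate fell or were backed by their other probe sets. Tnrc6a rose by 0.39 (SE 0.06, adjusted p = 0.0377), while its other probe sets ran from −0.10 to 0.26 without the covariate, most of them below 0. Lamtor1 rose by 0.28 (SE 0.05, adjusted p = 0.0473), beside 0.10 and 0.13. Ppfibp1 fell by 0.40 (SE 0.07, adjusted p = 0.0473), while its other probe set gave 0.08.

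Across the 6110 genes read by several tested probe sets, the log2 differences of the 2 brightest correlated with r = 0.291 across genes, which are not independent replicates, and 58.7% had the same sign. Among the 100 genes with the smallest p for either probe set 72% had the same sign, and the median ratio of the weaker to the leading difference was 0.149.

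Malat1, a long noncoding RNA held in the nucleus, averaged −0.29 over its 7 tested probe sets (95% exact permutation interval −0.48 to −0.10, exact p = 0.00649), 6 of them lower, in a range from −0.82 to 0.35. The hypothesis that p190B preparations may hold a lower share of nuclear RNA predicts that other nuclear-retained RNAs are lower too. The mean of Neat1, Xist, Kcnq1ot1 and Meg3, each read by its brightest probe set, was 0.14 higher in p190B (95% exact permutation interval −0.13 to 0.40, exact p = 0.255). This argues against a shared fall of the size averaged for Malat1 (−0.29). A smaller fall is not excluded, since the interval reaches −0.13. Tsix, also named beforehand, lay below the filter on signal and is not in the mean of these other RNAs.

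As a measure of chance, 100 of the 462 splits of the 12 arrays into equal groups were compared, the real one included. The genotype split gave 10 probe sets, 3 of the 100 splits gave as many or more, and 94 gave 0. Chance as the source of the count is therefore argued against only weakly. The highest other split gave 504, and 1 of 20 simulated runs with no change gave 1751. The split with 504 set 6 arrays apart with a difference of 1.83 log2 units in the lymphocyte markers, so a structure of the samples other than genotype can give more calls. For the gene lists the genotype split gave 0 by fry and the highest other split 3. All 100 splits give at least 0, so this count decides nothing about chance.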
